A study of Mus musculus with 4 samples.

How the data were processed

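The series profiled binding of phosphorylated Smad proteins in molar tooth germs of wild-type CD1 mouse embryos at embryonic day 13.5 by CUT&RUN. In this assay an antibody tethers micrococcal nuclease to chromatin, and the fragments cut around the bound sites are sequenced. The labels name 4 libraries, 2 made with an antibody against phosphorylated Smad1/5 (pSmad1/5) and 2 with an antibody against phosphorylated Smad3 (pSmad3). Per the labels' protocols, chromatin was digested for 30 min and libraries were sequenced as paired-end reads of 100 bp. The submitters' processing notes name Bowtie2, SAMtools, bedtools, SEACR, deepTools and the mouse build mm10, with no versions. Their settings, the SEACR threshold and any control library used for calling are not given in the sources used here.

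The authors deposited 1 peak list per antibody, which the labels describe as peaks common to the 2 libraries. Each line has a position and, in the layout of SEACR output, the total signal of the call, its maximum signal and the region of that maximum. The deposited total and maximum are coverage signal in the authors' own scaling, and they are the authors' values for each peak. They were used only to describe, rank or filter peaks within a list, never to compare the antibodies. Signal percentiles rank peaks by total signal, which can be high in a long call whose maximum is near or below the list median. Lines that share total, maximum and maximum region are pieces of 1 call. The pSmad1/5 list held 10741 lines from 8380 calls, of which 1695 were in several pieces (at most 21), and the pSmad3 list held 7905 lines from 7682 calls, of which 211 were in several pieces. Each deposited line is called a peak below. The region of the maximum lay inside the peak for 27.1% of pSmad1/5 peaks (exact 95% Clopper-Pearson interval 26.3 to 28.0) and 70.0% of pSmad3 peaks (68.9 to 71.0), so the signal of a peak is that of its call. How the lists of the libraries were joined is not given in the sources used here, so these signals, and every percentile drawn from them, may come from the call of 1 library. No value per library was used here, and read depth is unknown. Intervals on shares of peaks cover counting error only. Like the tests that count or place peaks, they treat pieces of 1 call as separate, so they may understate the uncertainty.

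Genes were placed with the RefSeq gene table of GRCm38.p6, the same assembly as mm10. It gives the start and end of each gene but no strand, exons or sequence. Of 49997 genes in the table, 49214 were placed on chromosomes 1 to 19 and X, among them 21523 protein-coding and 12609 lncRNA genes used in the tests below. Genes listed within the first 3 Mb of a chromosome were left out, since these belong to unlocalised scaffolds. The Y chromosome was left out of the gene tests. Because the strand was unknown, every test planned around transcription starts used the nearer of both gene ends, and classes were near a gene end (within 1 kb), inside a gene or outside genes. Tests planned on DNA sequence were not run.

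Overlap was counted as at least 1 bp between a peak of one list and any peak of the other, on chromosomes 1 to 19, X and Y. It was compared with 1000 random placements of the other list within its chromosomes, widths kept, in a two-sided permutation test whose smallest possible p is 0.002. The same number of placements was used for the position of the maximum relative to genes. For gene lists, a gene had a peak if the peak touched the gene body or 10 kb on either side, called the locus below. The number of list genes with a peak was compared with 10000 random lists of protein-coding genes matched on locus length in 20 bins (two-sided permutation test, smallest p 0.0002), and p was adjusted by the Benjamini-Hochberg method over the 29 lists. The difference between the numbers of genes with a pSmad1/5 and with a pSmad3 peak was tested against the same random lists. The lists were fixed before the data were examined: targets of each branch, pathway components, dental and other cell type markers, pathways, gene families and control lists. Whether Smads bind the genes of the target lists directly was not checked. All these tests compare deposited lists with random placement or random genes. With 1 list per antibody there was no replicate check, and none of the p-values measures spread between embryos or libraries.

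Named genes were chosen by a rule fixed before the data were examined. It took from each list up to 5 members with a peak, by the highest signal percentile within a list of peaks, and up to 3 without. It added the nearest genes of the 10 peaks with the highest total signal in each list, of the 10 highest unshared peaks, the 5 genes with the most peaks per list, and a fixed set of tooth and Smad target genes. Some genes the rule takes are not reported here. A gene outside the rule is said to be chosen after its values were seen. The alternatives covered the minimum overlap, stricter peak lists, the definition of a locus and the kind of random placement.

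Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The methods were tested on simulated data. With 500 overlaps planted, 500 were recovered, and 0 of 20 simulated pairs of unrelated lists gave p at or under 0.05. Those pairs were placed peak by peak as in the test itself, so they do not cover clustered peaks or pieces of calls. For simulated lists of 22 genes tested for pSmad3 peaks among 21523 genes, p was at or under 0.05 in 4.5% of lists with no change, 58% with the share of genes near a peak doubled and 100% with it tripled. The test of the difference between antibodies reached that level in 5.5%, 16% and 71%. The simulated lists drew single genes at random, so they do not cover clustered gene families.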

Results

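The data are 2 peak lists from CUT&RUN on mouse molar tooth germs at E13.5 (embryonic day), when the dental epithelium buds into the condensing mesenchyme. One list was made with an antibody against pSmad1/5, the Smads phosphorylated by BMP receptors. The other was made with an antibody against pSmad3, phosphorylated by TGF-β and activin receptors. Each stands for 2 libraries, and no value per library was used here. The pSmad1/5 list held 10741 peaks with a median width of 2385 bp (interquartile range 1829 to 3007), covering 30.1 Mb. The pSmad3 list held 7905 peaks with a median width of 4693 bp (2892 to 6060), covering 41.8 Mb. The comparisons ask which regions and genes each Smad branch occupies in the early tooth, and which are shared.

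Most peaks had no overlapping peak in the other list, but the lists met far more often than random placement gives. A missing peak means no deposited call, as signal under the calling threshold was not examined. Of 10615 pSmad1/5 peaks on chromosomes 1 to 19, X and Y, 2322 overlapped a pSmad3 peak, or 21.9% (exact 95% interval 21.1 to 22.7). Random placement gave 289 on average (255 to 324 in 95% of placements), an 8.04-fold difference. Of 7836 pSmad3 peaks, 1812 overlapped a pSmad1/5 peak, or 23.1% (22.2 to 24.1), against 286 (256 to 318), a 6.34-fold difference. Both permutation p-values were 0.002, the smallest possible. Counted as distinct calls, 1668 of 8313 pSmad1/5 calls (20.06%) and 1764 of 7620 pSmad3 calls (23.15%) overlapped, without a random placement of whole calls. Peaks moved by only 20 to 100 kb, an alternative added after the data were seen, still overlapped 1060 and 904 times, so the excess was 2.19-fold and 2.0-fold against that local placement. Shared peaks had higher signal within their own list. Their median total signal was 94564 against 50456 for unshared pSmad1/5 peaks and 39030 against 27083 for unshared pSmad3 peaks, each above all 10000 random draws of as many peaks. Shared peaks were also wider, with medians of 2739 against 2319 bp for pSmad1/5 and 5544 against 4488 bp for pSmad3. Weighted to the widths of the shared peaks, the unshared medians of total signal were 51707 and 30189, still lower. These are widths of deposited lines, while total signal is that of the whole call. Call length was not matched, so the weighting cannot decide whether longer calls account for the difference.

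**Figure D1:**
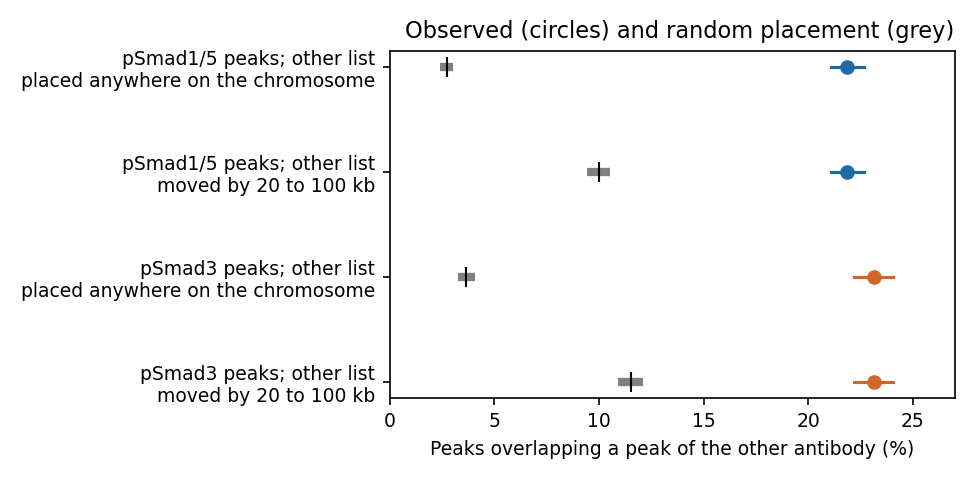
Share of peaks (%) of each list that overlap a peak of the other by at least 1 bp. Circles are observed shares with exact 95% intervals, grey bars the central 95% of 1000 random placements and ticks their mean. Observed shares of 21.9% and 23.1% lie above random placement both across the chromosome and within 20 to 100 kb.

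TGF-β target genes had pSmad3 peaks more often than random genes, and more often than pSmad1/5 peaks. Of the 22 genes on this list, 13 had a pSmad3 peak in their locus, where random lists gave 5.50 on average (2 to 10; permutation test, adjusted p = 0.0058). Only 3 had a pSmad1/5 peak (5.97 expected, adjusted permutation p = 0.864), and all of these also had a pSmad3 peak, so 10 genes had pSmad3 alone and 0 had pSmad1/5 alone. Here and below, alone means that the other list had no peak in the locus, not that its signal was absent. The difference of -10 genes (pSmad1/5 minus pSmad3) had an adjusted p of 0.0058, and this was the only 1 of the 29 lists in which the antibodies differed past the threshold of 0.05. Members with pSmad3 alone included Cdkn1a, a cell cycle inhibitor, Scx, a tendon transcription factor, Smad7, an inhibitory Smad that is also on the list of BMP targets, and Col1a1, a chain of type I collagen.

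At Cdkn1a (chromosome 17, 29090979 to 29100722, mm10) a pSmad3 peak ran from 29094689 to 29104109 over a gene end, with a total signal above 95.4% of the list. Scx had 2 pSmad3 peaks, the stronger 2325 bp outside the gene on chromosome 15 (76461793 to 76464109, percentile 90.7). The pSmad3 peak of Smad7 lay inside the gene on chromosome 18 (75372117 to 75378333, percentile 80.4). The maximum signals of these peaks were 25 at Cdkn1a, 14 at Scx and 11 at Smad7, against a list median of 13 (quartiles 12 and 15). Ski, a repressor of Smad signalling, had 4 pSmad3 peaks (highest percentile 91.6) and 1 pSmad1/5 peak 7077 bp outside the gene, inside the span of a pSmad3 peak. Ltbp2, a latent TGF-β binding protein, had 3 pSmad3 and 5 pSmad1/5 peaks (3 and 4 calls), and Pmepa1, a feedback inhibitor of TGF-β signalling, had 1 and 3 (1 and 2 calls). The remaining genes with pSmad3 alone, named after their values were seen, were Ltbp3, Klf10, Ccn1, Tgfbi, Junb and Tagln. Skil and Ccn2, both well known TGF-β targets, had neither.

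**Figure D2:**
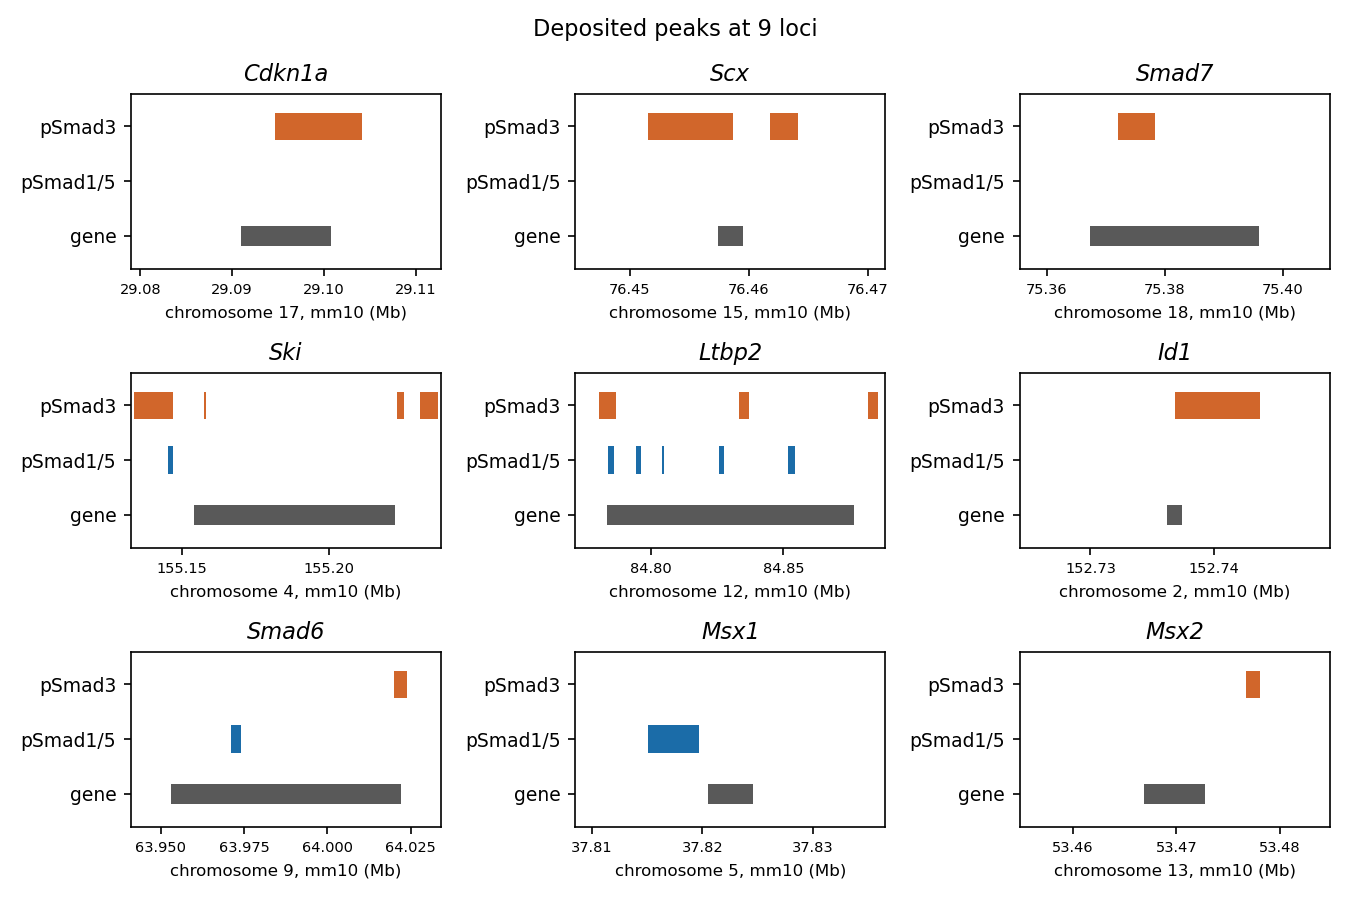
Deposited peaks at 9 loci along mm10 coordinates (Mb), with the gene body in grey, pSmad1/5 peaks in blue and pSmad3 peaks in orange. Cdkn1a, Scx and Smad7 have pSmad3 peaks alone, while Ski, Ltbp2 and Smad6 have peaks of both antibodies.

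BMP target genes did not stand out for either antibody. Of 20 genes, 5 had a pSmad1/5 peak (4.94 expected) and 5 a pSmad3 peak (4.56 expected), with an adjusted p of 1 for each and for the difference. Id1, an inhibitor of basic helix-loop-helix factors and a standard BMP readout, had a pSmad3 peak over a gene end on chromosome 2 (152736834 to 152743752, percentile 53.4) and no pSmad1/5 peak. Id2, Id3 and Id4 had neither. Smad6, the inhibitory Smad of the BMP branch, had a pSmad1/5 peak inside the gene on chromosome 9 (63971032 to 63974172, percentile 73.3) and a separate pSmad3 peak over a gene end (64019903 to 64023777). Smad7, on this list too, had its pSmad3 peak alone. Atoh8 had 2 pSmad1/5 peaks, the stronger 3691 bp outside the gene, and Tbx2 had 2 pSmad1/5 peaks from 1 call and 1 pSmad3 peak. Among 44 BMP and TGF-β pathway components, 13 had a pSmad1/5 and 11 a pSmad3 peak (13.8 and 12.5 expected). Bmp7 had 4 and 3 peaks (3 and 3 calls), Tgfb3 2 and 1, and Eng, a co-receptor, 3 and 3 (2 and 3 calls), while Bmp2, Bmp3 and Bmp4 had none.

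Genes that mark the dental mesenchyme did not stand out from other genes. Of 41, 27 had neither antibody's peak (65.9%), against 62.4% of all protein-coding genes, 8 had a pSmad1/5 peak (12.1 expected, adjusted permutation p = 0.864) and 9 a pSmad3 peak (10.6 expected, adjusted p = 1). Pax9, Lef1, Dlx1, Dlx2, Osr2 and Bmp4, all transcription factors or signals of the early tooth mesenchyme, were among those without. Msx1, required for tooth development past the bud stage, had a pSmad1/5 peak 795 bp outside the gene on chromosome 5 (37815083 to 37819696). It was low in its list by total signal (percentile 16.6), but its maximum of 18 lay above the list median of 16. Msx2 had a pSmad3 peak 3925 bp outside the gene (percentile 22.4, maximum 15 against a list median of 13). Runx2, a bone and tooth regulator, had a pSmad1/5 peak inside the gene at percentile 5.7 (maximum 14). Gli2, a transcription factor of the Hedgehog pathway, had 5 pSmad1/5 and 6 pSmad3 peaks and Gli1 2 and 1, while Sdc1 had pSmad1/5 alone.

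Dental epithelium markers had more pSmad1/5 than pSmad3 genes, but the difference did not hold after adjustment. Of 30 genes, 11 had a pSmad1/5 peak (8.45 expected) and 3 a pSmad3 peak (7.57 expected), and the difference of 8 genes had an adjusted p of 0.209. Krt14, a basal keratin, had a pSmad1/5 peak over a gene end (percentile 77.1), Cldn4, a tight junction protein, one 9710 bp outside the gene (82.1), and Esrp1, an epithelial splicing regulator, one inside (68.1). Their maxima were 14, 24 and 15, against a list median of 16. Grhl3, an epithelial transcription factor, had peaks of both antibodies. Shh, the signal of the dental placode and enamel knot, had a pSmad1/5 peak at percentile 0.4, close to the lowest total signal in the list (maximum 14). Krt5 and Krt18 had none.

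Genes of the Hedgehog and Notch pathways had pSmad3 peaks more often than random genes. In the Hedgehog list 12 of 21 genes had one (6.00 expected, adjusted permutation p = 0.0456), and in the Notch list 13 of 25 (6.39 expected, adjusted p = 0.0406). Hedgehog genes with a pSmad3 peak included Gli1 over a gene end (percentile 89.5), Hhat with 3 peaks (82.4) and Kif7 over a gene end (76.7). Smo, the pathway's signal transducer, had 5 pSmad1/5 peaks from 2 calls and 1 pSmad3 peak, with maximum signals of 1009 and 763 against list medians of 16 and 13. High-copy sequence, present many times in the genome, is a candidate source of maxima over 10 times the median, as at Smo. Among Notch genes, the receptor Notch1 had 2 pSmad3 peaks (91.8) and the ligand Jag2 2 (76.3), while Dll1, Hes1 and Hes6 had none. The pSmad1/5 counts were 9 (6.78 expected) and 10 (7.20 expected), not past the threshold, and the antibodies did not differ (adjusted permutation p = 0.516 for both lists). Both pSmad3 calls ended when a peak had to lie within 5 kb of a gene end, with 6 (3.2 expected, adjusted permutation p = 0.424) and 9 genes (3.96 expected, 0.134), and with the stronger peaks alone, with 9 (3.52 expected, 0.0557) and 8 (3.76 expected, 0.196). In each of these settings fewer genes were expected to have a peak. Hedgehog genes also lost the call without peaks over 2 times the median maximum (11 genes, 5.83 expected, adjusted permutation p = 0.102) and Notch genes with peak midpoints (11 genes, 5.94 expected, 0.146). Leaving out those high peaks took out the only pSmad3 peak of Smo. Across the 6 alternatives the adjusted p ran from 0.00193 to 0.424 for Hedgehog and from 0.00435 to 0.196 for Notch.

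**Figure D3:**
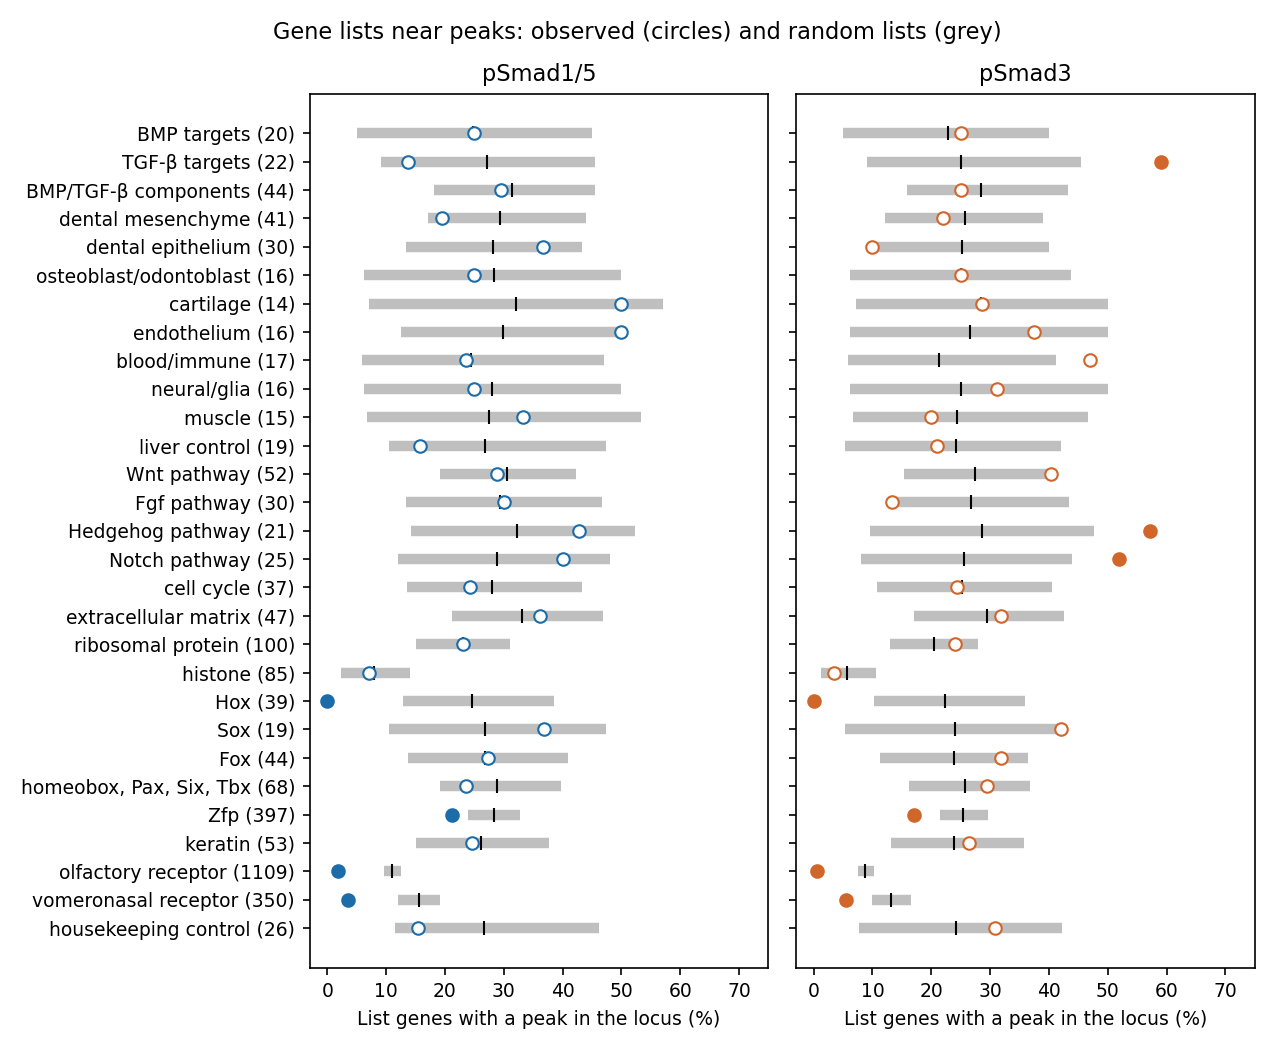
Share of genes (%) in each list with a pSmad1/5 peak (left) or a pSmad3 peak (right) in the locus, with list sizes in parentheses. Circles are observed shares, filled where the adjusted p is at or under 0.05, grey bars the central 95% of 10000 random lists and ticks their mean. Filled circles lie above random lists for 3 lists and below for 4 with pSmad3, and below for 4 with pSmad1/5.

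Several clustered gene families had fewer genes with peaks than random lists, for both antibodies. None of the 39 Hox genes had a peak (9.62 and 8.70 expected, adjusted permutation p = 0.00193 and 0.00145). These genes lie in 4 clusters, and moved as clusters the absence did not pass the test (permutation p = 0.374 for pSmad1/5 and 0.53 for pSmad3). Only 1.3 and 1.1 clusters were expected to have a peak, so even a complete absence could not pass, and this test cannot decide. Of 1109 olfactory receptor genes, 20 had a pSmad1/5 and 7 a pSmad3 peak (122 and 97.7 expected), and of 350 vomeronasal receptor genes, 12 and 19 (54.4 and 46.2 expected). Of 397 Zfp zinc finger genes, 84 and 68 had a peak (112 and 101 expected, adjusted permutation p = 0.0131 and 0.00145). The regions spanned by Zfp gene runs nevertheless held more peaks than expected, 325 for pSmad1/5 (162 expected) and 229 for pSmad3 (122 expected, permutation p = 0.002 for both, the smallest possible), and counted as distinct calls 215 and 210 (128 and 119 expected). Zfp993 alone had 28 pSmad1/5 peaks from 12 calls and 10 pSmad3 peaks, and Zfp978 19 from 12 calls and 11 from 6. The regions of the receptor runs held fewer peaks than expected, 32 and 17 for olfactory (145 and 112 expected, permutation p = 0.002 for both) and 37 and 41 for vomeronasal receptors (131 and 98.9 expected, p = 0.002 and 0.02). With each run counted once, an alternative added after the data were seen, 58 and 48 of 177 Zfp runs had a peak (46.6 and 41.2 expected, permutation p = 0.044 and 0.216) and 16 and 16 of 30 vomeronasal runs (15.5 and 14.1 expected, p = 0.989 and 0.52). Of 54 olfactory runs, 21 had a pSmad1/5 peak (23.9 expected, permutation p = 0.438) and 12 a pSmad3 peak (21.6 expected, p = 0.002). The Zfp deficit per gene also lost its call within 5 kb of a gene end, with 61 and 54 genes (73.8 and 70.2 expected, adjusted permutation p = 0.699 and 0.153). By nearest gene end within 100 kb it lost it with 84 and 71 genes (99.7 and 85.5 expected, adjusted permutation p = 0.192 and 0.209). The pSmad1/5 call was also lost with peak midpoints (84 genes, 108 expected, adjusted permutation p = 0.0522), and the pSmad3 call with the stronger peaks alone (48 genes, 57.7 expected, 0.425). The Hox deficit lost its call with the stronger peaks alone, still with 0 genes for both antibodies (5.34 and 5.07 expected, adjusted permutation p = 0.0536 and 0.0557). The vomeronasal pSmad3 deficit lost its call by nearest gene end within 100 kb (29 genes, 39.1 expected, adjusted permutation p = 0.209).

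Peaks of both antibodies lay closer to genes than random placement gives. The maximum lay within 1 kb of a gene end for 11% of pSmad1/5 peaks (10.4 to 11.6, 5.06% expected) and 10.7% of pSmad3 peaks (10.03 to 11.4, 5.12% expected). It lay inside a gene for 53.3% and 55.7% (45.2% and 45.3% expected, permutation p = 0.002 throughout, the smallest possible). Against peaks moved by 20 to 100 kb, an alternative added after the data were seen, the excess was smaller, with 8.38% and 8.64% expected near a gene end and 52.2% and 53.3% inside a gene. The median distance to a gene end was 9.45 kb and 8.85 kb, against 23.2 kb and 22.9 kb for random positions. Of 21523 protein-coding genes, 5874 had a pSmad1/5 peak in the locus (27.3%), 5248 a pSmad3 peak (24.4%) and 3032 both, where lists independent at each locus length would share 1555.

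The strongest signals were common to both antibodies and lay mostly far from protein-coding genes. The highest total signal in each list belonged to the same place on chromosome 2, from 98661919 to 98668289 in the pSmad3 list, over 1 Mb from its nearest protein-coding gene, Lrrc4c. Its maximum was 2249140 for pSmad1/5 and 1736980 for pSmad3, against list medians of 16 and 13. Other high peaks of both lists lay at the start of the assembled part of chromosome 9 (from 3000001), on chromosome 14 near 19415627, on chromosome 12 near 3108317 and inside Chl1, a neural adhesion gene, on chromosome 6. High-copy sequence, present many times in the genome, is a candidate source. No such places were masked here, so these signals cannot be read as Smad binding. Peaks with a maximum over 2 times the list median made up 8.98% of the pSmad1/5 and 5.97% of the pSmad3 list. On the chromosomes compared, 77.7% of these pSmad1/5 peaks were shared (74.8 to 80.4) against 16.9% of the others (16.2 to 17.7), and 92.1% of these pSmad3 peaks (89.1 to 94.5) against 19.2% (18.4 to 20.2). Without them 1571 pSmad1/5 and 1325 pSmad3 peaks overlapped.

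Peak density varied between chromosomes. It ran from 2.05 to 6.35 pSmad1/5 peaks per Mb and from 1.57 to 5.04 pSmad3 peaks per Mb over the autosomes, with chromosome 3 lowest for both, chromosome 17 highest for pSmad1/5 and chromosome 4 highest for pSmad3. The X chromosome had 0.554 and 0.262 peaks per Mb.

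**Figure D4:**
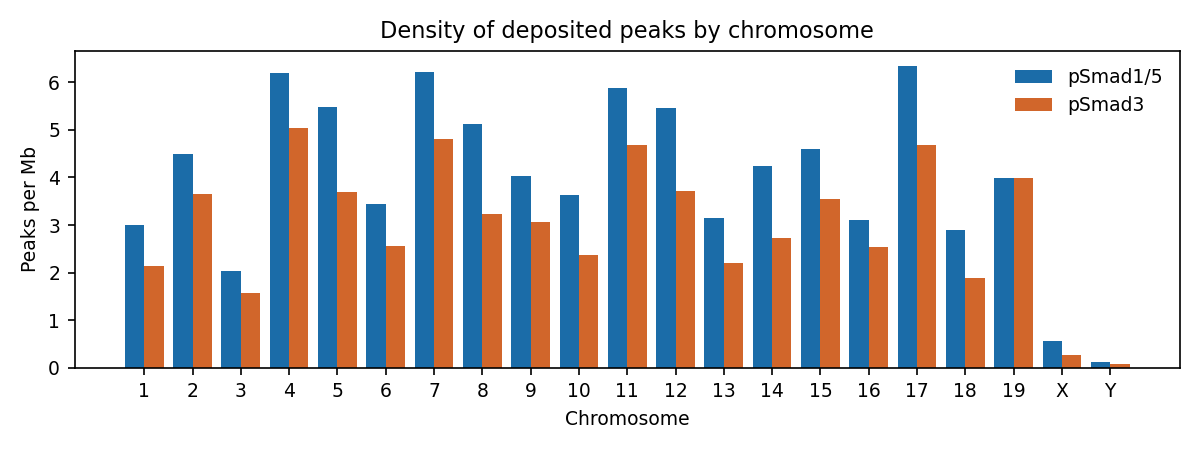
Peaks per Mb on each chromosome for pSmad1/5 (blue) and pSmad3 (orange). The X chromosome, at 0.554 and 0.262, lies below every autosome, and Y lies lower still.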

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

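The tests of gene density and of active genes below were chosen after the result was seen, and the peak midpoint setting was added after the data were seen, with its bound set before its result.

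TGF-β target genes differed between the antibodies, with 3 genes near a pSmad1/5 peak and 13 near a pSmad3 peak, a difference of -10. Wider pSmad3 peaks could reach more loci, but random lists were scored with the same peaks, so width was already in the expectation. With each peak reduced to its midpoint the counts stayed at 3 and 13 and the adjusted permutation p of the difference was 0.0058. Matching random lists on gene density as well gave 0.0058. The unadjusted permutation p was 0.0002, the smallest possible, in each setting, so these p-values cannot show whether the difference weakened. Of 209 housekeeping, ribosomal protein, matrix and dental mesenchyme genes, 55 had a pSmad3 peak (26.3%), a lower share than 13 of 22 TGF-β targets (59.1%, Fisher's exact test, two-sided, p = 0.00256). Of the 209 genes, 100 were ribosomal protein genes, and locus length was not matched. Among the other lists the highest shares were Hedgehog 12 of 21, Notch 13 of 25 and blood and immune 8 of 17. A high pSmad3 share was thus not particular to TGF-β targets. Activity of any of these genes in the tooth germ was not measured here, so binding of pSmad3 at any active gene stays open. Different antibodies, with 1 list each and no control list used here, stay open too. A branch-specific binding of pSmad3 at its own targets may remain as a hypothesis, found and tested on the same lists.

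Outside the chromosomes compared, 125 pSmad1/5 and 68 pSmad3 peaks lay on unplaced or unlocalised contigs, which no comparison used.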

How the results depend on the processing

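No paired analysis was possible because the labels number the libraries of each antibody 1 and 2 but the files hold 1 list per antibody, so the replicate block and leaving out each library were not run. Motif tests and their alternatives (other window sizes, matched windows, peaks away from promoters, stronger unshared peaks) and matching on promoter CpG content were not run for want of sequence. Settings with midpoints, without high peaks, matched on gene density, with local moves, counting runs or distinct calls, and the stronger peaks for the difference between antibodies, were added after the data were seen. Of 69 tested alternative values for the main results, 63 stayed on the same side of the threshold. A value past the threshold in neither setting could count among these even if its direction changed. The number of lists past the threshold ran from 3 to 6 for pSmad1/5 (main value 4), from 3 to 8 for pSmad3 and stayed at 1 for the difference. For pSmad3 it fell from 7 to 4 within 5 kb of a gene end and to 3 with only peaks above the median total signal. Hedgehog genes near pSmad3 peaks lost their call at 6 of 21 within 5 kb (3.2 expected), 9 with the stronger peaks (3.52) and 11 without peaks over 2 times the median maximum (5.83). Notch genes lost theirs at 9 of 25 within 5 kb (3.96 expected), 8 with the stronger peaks (3.76) and 11 with midpoints (5.94). Counted once per run, with runs moved in place of random gene lists, Zfp genes turned from below to above expectation (58 runs for pSmad1/5, 46.6 expected, and 48 for pSmad3, 41.2 expected). Vomeronasal receptors came near expectation (16 and 16 runs, 15.5 and 14.1 expected). Neighbours then no longer count separately, but the kind of random placement changed too, so the 2 changes cannot be told apart. The cause of the other changes was not tested. Overlap counts that moved most were 641 and 641 with reciprocal overlap of 50% (100 placements), 529 and 344 for maximum regions, 1417 and 979 above the median total signal and 1421 and 987 by maximum, each above random placement. The TGF-β difference ran from -10 to -7 and kept its call, with -7 (adjusted permutation p = 0.0174) for the stronger peaks. By nearest gene end within 100 kb, Wnt, endothelial, Sox, Fox and homeobox lists gained calls given with those lists. For other lists, 83 of 106 tested values stayed on the same side of the threshold, counted in the same way. Of the rest, 7 gained a call, 12 lost theirs in the same direction and 4 reversed direction. Of 244 pairs of named gene and antibody with a peak, 164 kept one within 5 kb of a gene end.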

Other observations

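The tests of X copy number and of regional density below were chosen after the result was seen. Local moves, and leaving out peaks with high maxima, were settings added after the data were seen.

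Wnt pathway genes were near a pSmad3 peak in 21 of 52 cases (14.2 expected, permutation p = 0.056, adjusted p = 0.18), with 15 near a pSmad1/5 peak (15.8 expected). Wnt3 had 3 pSmad1/5 and 3 pSmad3 peaks (2 and 3 calls), and Nkd1, an inhibitor of Wnt signalling, 2 and 2 (1 and 2 calls). Nkd2 had a pSmad1/5 peak at percentile 91.3, while Wnt2, Wnt5a and Wnt6 had none. Blood and immune markers had 8 of 17 genes near a pSmad3 peak (3.63 expected, adjusted permutation p = 0.109), and 4 near a pSmad1/5 peak (4.16 expected). Spi1, Csf1r, C1qa and Cd68 had a pSmad3 peak, while Ptprc, Tyrobp and Itgam, which also mark leukocytes or myeloid cells, had neither. Endothelial markers had 8 and 6 of 16 (4.79 and 4.26 expected), including Cdh5, Eng, Vwf and Egfl7. Cartilage markers had 7 and 4 of 14 (4.5 and 3.99 expected), among them Col2a1, Matn1, Sox5 and Sox6, while Sox9 had neither. None of these passed the threshold after adjustment with the locus of 10 kb on each side. With each peak given to its nearest gene end within 100 kb, Wnt genes passed for pSmad3 (22, 12.9 expected, adjusted permutation p = 0.0217) and endothelial markers for pSmad1/5 (10, 4.45 expected, 0.0319).

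Remaining lists did not pass the threshold with that locus either. Osteoblast and odontoblast markers had 4 and 4 of 16 genes near pSmad1/5 and pSmad3 peaks, neural and glial markers 4 and 5 of 16, muscle markers 5 and 3 of 15 and Fgf pathway genes 9 and 4 of 30. Matrix genes had 17 and 15 of 47, with 7 and 4 peaks (3 and 4 calls) at Hspg2 (perlecan) and 5 and 5 (4 and 4 calls) at Fbln2. Cell cycle genes had 9 and 9 of 37. Sox genes had 7 and 8 of 19, Fox genes 12 and 14 of 44, homeobox, paired-box and T-box genes 16 and 20 of 68, and keratins 13 and 14 of 53. Ribosomal protein genes had 23 and 24 of 100 and histone genes 6 and 3 of 85. Among controls, liver genes had 3 and 4 of 19, with none at Alb, and housekeeping genes 4 and 8 of 26. The adjusted p was at least 0.109 for pSmad3 and at least 0.808 for pSmad1/5 in all the lists named here. By nearest gene end within 100 kb, Sox genes passed for pSmad1/5 (12, 4.27 expected, adjusted permutation p = 0.00145), Fox genes for both antibodies (18 and 17, 10.04 and 8.24 expected, 0.0319 and 0.0058) and homeobox, paired-box and T-box genes for pSmad3 (25, 14.5 expected, 0.0199). Sox genes also passed for pSmad3 with random lists matched on gene density (8, 3.32 expected, adjusted permutation p = 0.045).

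Some regions held many peaks of both antibodies. Of all 1 Mb windows, 3 held the most pSmad1/5 peaks, 56 each, many of them pieces of the same calls. They were chromosome 4 from 147 Mb, with Zfp978 and other zinc finger genes (32 calls), chromosome 1 from 85 Mb, with Sp100, Sp110 and Sp140 (17 calls), and chromosome 17 from 6 Mb, with Dynlt1a, Dynlt1b and Dynlt1c (19 calls). They held 24, 23 and 21 pSmad3 peaks. The most pSmad3 peaks, 32 from 28 calls, lay on chromosome 2 from 177 Mb, where pSmad1/5 had 7. Windows with at least 20 peaks numbered 87 for pSmad1/5, with 22.5% of its peaks, and 42 for pSmad3, with 12.7%. Outside such gene families, Camta1 had 18 and 12 peaks (16 and 12 calls), Rbfox3 17 and 13 (13 and 12 calls), and Cdh23 12 and 12 (10 and 11 calls). These places were chosen after their values were seen, except Zfp978, Dynlt1b, Camta1, Rbfox3 and Cdh23.

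The overlap of the lists was weighed against shared density. Peaks moved by 20 to 100 kb kept regional density, and the observed pSmad1/5 overlap was 2.19 times theirs, which argues against regional density as the whole cause. High-copy sequence is a candidate source. The maxima of 100 of 168 pSmad1/5 calls over 10 times the median maximum lay within 10 bp of a pSmad3 maximum (59.5%, 51.7 to 67.0), against 52 of 8212 others (0.633%, 0.473 to 0.830). Sites open to the nuclease could give coinciding maxima too, and copy number was not measured, so these values do not single out high-copy sequence. Without peaks over 2 times the median maximum the overlap was still 2.10 times that of local placement, so these peaks are not its whole cause. High-copy sequence with lower maxima would pass this filter, so it stays open as a source. Sites open to the nuclease with any antibody stay open, as no control list was used here.

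The X chromosome held few peaks of either antibody. It had 93 pSmad1/5 peaks, or 0.554 per Mb against 4.37 on autosomes (2.05 to 6.35 over single autosomes), and 44 pSmad3 peaks, or 0.262 against 3.24 (1.57 to 5.04). Low gene density is argued against as the whole cause, since autosomal 1 Mb windows matched on gene number held 576 pSmad1/5 peaks on average and X windows 86, a ratio of 0.149. A lower copy number, which may bring weak peaks under the calling threshold, went with a higher X share among peaks over 2 times the median maximum, 2.09% against 0.77% (Fisher's exact test, two-sided, p = 0.000417), and 4.63% against 0.337% for pSmad3 (p = 1.28e-13). Any cause that lowers unique signal on X would give the same, and the sex of the embryos is not given in the sources used here.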
